A study of Mus musculus with 4 samples.

How the data were processed

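Ovarian immune cells of 1 control and 1 letrozole-treated (PCOS model) group of female mice were measured, with 1 gene expression and 1 TCR library per group, prepared with the 10x Genomics Chromium 5' and V(D)J workflows, per the labels. The deposited matrices hold raw UMI counts per gene and barcode for 32285 genes. Cell Ranger 8.0.0 with builds GRCm38 and mm10 is named in the submitters' processing notes, together with Seurat, whose version is not given in the sources used here. The deposited TCR files hold counts of UMIs and reads per contig, the number of barcodes per clonotype, and each clonotype's fraction of the library, per the file headers. Gene names are those paired with identifiers in the deposited feature files.

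The main choices, the gene lists, the markers and the rule for named genes were fixed before the data were examined. Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs, which removed 14.2% of control and 9.08% of PCOS-model barcodes. Scrublet marked 3 of 12047 barcodes as doublets (0.0249%), so doublet calling has not worked, and doublets remain among the 12044 cells. An alternative therefore removed the highest Scrublet scores at 0.8% per 1000 barcodes (94 and 693 barcodes). Cells of both libraries were clustered together on counts scaled to 10000 and log-transformed, with 2000 variable genes chosen without TCR, immunoglobulin, mitochondrial and ribosomal genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1.0, which gave 28 clusters. Clusters were named from fixed markers, and those without clear markers, or with more markers of another class than of their own among their top 10 genes, stayed unnamed. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

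An alpha-beta T cell was a kept barcode with a productive TRB contig. A CD8 T cell had at least 1 UMI of Cd8a or Cd8b1 and 0 of Cd4, and a CD4 T cell the reverse. CD8 T cells were clustered again at resolution 0.8, giving 10 subclusters. UMIs were summed per library and class and scaled to a fixed total, as CPM. Log2 ratios are PCOS model over control with 0.5 UMI added to each sum. No test, p-value or count of changed genes was made, since each group has 1 library. Shares have exact binomial (Clopper-Pearson) intervals, sums exact Poisson intervals and ratios exact conditional intervals, all at 95% and for counting error only. A count of 0 was given a floor of 3 counts over the group. Named genes were the 12 highest and 12 lowest log2 ratios in CD8 T cells among genes with at least 50 UMIs over both libraries and at least 50 CPM in 1 of them, the 6 highest and 6 lowest in CD4 T cells and in the 3 other classes with most cells in the smaller library, up to 3 members of a list, all virtual memory genes, and Itga4. TCR, immunoglobulin, mitochondrial, ribosomal, haemoglobin and unnamed genes were left out of the ranking.

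List medians used members with at least 20 UMIs and were placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Lists covered naive T, virtual memory, effector memory, tissue residency, cytotoxicity, cytokines and chemokines, inhibitory receptors, JAK-STAT, interferon response, early activation, dissociation stress, proliferation, steroid receptors and response, macrophage inflammation, class II antigen presentation and lipid handling. Markers of granulosa, theca and luteal, ovarian stroma, endothelial, pericyte and smooth muscle, epithelial, oocyte, erythroid and platelet cells were summed to look for free RNA. The list and ratio steps were tested on simulated data for the CD8 T cell comparison (9672 genes, 200 of them changed). Of 50 genes at each fold, 100% kept their sign, and the 95% interval covered the true log2 value for 88% at -2, 96% at -1, 100% at 1 and 98% at 2. Of 200 unchanged lists, 5% fell in the outer 5% of random lists. The simulated sums were independent Poisson draws per gene, and the unchanged lists were drawn at random. Co-expression of list members and differences in cell make-up were not simulated, so the percentiles and intervals were not checked for these.

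Clonotypes were taken as deposited, with 2 or more barcodes counted as shared, and libraries were also thinned to the same number of barcodes in 1000 draws. V genes were counted from the productive contig with most UMIs per chain and barcode, and the 5 largest differences per chain were named. Alternatives changed the cell filter, doublets, resolution, denominator, gate, depth, scaling, count minimum and clonotype definition. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.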

Results

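Immune cells from the ovaries of female wild-type mice were profiled by droplet 5' gene expression sequencing together with T cell receptor (TCR) sequencing of the same cell suspensions. One group received vehicle (control) and the other received letrozole, an aromatase inhibitor that lowers oestrogen synthesis and gives a model of polycystic ovary syndrome (PCOS model). Each group had 1 expression library and 1 TCR library. The control expression library held 3696 barcodes with 18612389 UMIs, and the PCOS-model library held 9764 barcodes with 41244602 UMIs. After filtering, 3167 and 8877 cells remained, with median depths of 3872 and 3925 UMIs and medians of 1688 and 1623 genes per cell. The TCR libraries held 984 and 2195 barcodes in 880 and 2113 clonotypes. With 1 library per group, no difference below has a replicate check and none was tested. Intervals are exact 95% intervals that cover counting error only. Cells had been enriched or sorted by a gate that the labels do not name, and such a gate can set any of the shares.

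The first comparison asked which immune cells differed in share between the libraries. CD8 T-like cells were the largest population of the PCOS-model library and a smaller one in the control library. Naive cells (Ccr7, Lef1), virtual memory cells (memory-like CD8 T cells that form without meeting a foreign antigen, marked by Il2rb, Eomes and Ly6c2) and interferon-high cells were each a larger share of all kept cells in the PCOS-model library. Cells with the genes of thymocytes (Rag1, Dntt, Ptcra) were the largest named population of the control library. CD8 T-like cells were 8.18% of control cells (7.25 to 9.19) and 48.2% of PCOS-model cells (47.2 to 49.3), a log2 ratio of 2.56. At the coarser clustering resolution of 0.5 they were 15.6% and 50.7% (log2 ratio 1.70). The class differed in make-up: a Cd8a or Cd8b1 UMI was read in 71.0% of its control and 95.5% of its PCOS-model cells, at median depths of 5514 and 4620 UMIs. The naive cluster made up 3.73% and 20.8%, the virtual memory cluster 1.89% and 14.8%, and the interferon-high clusters 2.56% and 12.6%. Within the CD8 T-like class, naive cells were 118 of 259 and 1850 of 4282, and interferon-high cells 81 and 1122. Neither was a larger part of the class in the PCOS-model library. Thymocyte-like cells, proliferating ones included, made up 24.3% (22.8 to 25.8) and 7.75% (7.20 to 8.33), a log2 ratio of -1.65. B-like cells were 14.1% and 7.28%, CD4 and regulatory T-like cells 9.98% and 5.49% (with Cd4 at 232 and 137 CPM, Cd8a at 105 and 375 CPM and Cd8b1 at 129 and 381 CPM), NK-like cells 5.87% and 2.82%, and neutrophil-like cells 7.14% and 5.72%. Macrophage-like cells were 3.06% and 2.11%, dendritic cell-like cells 2.75% and 1.34%, gamma-delta T-like cells 1.17% and 0.845%, and plasma-like cells 0.853% and 0.406%. Stroma-like, epithelial-like, granulosa-like, endothelial-like and erythroid-like cells and 1 unnamed non-immune cluster together were 10.1% and 3.89%, although erythroid-like cells alone were 0.189% and 0.563% (6 and 50 cells). Unnamed T cell clusters held 12.5% and 14.1%, and the largest of them, in which the non-coding transcript AY036118 ranked first, held 7.96% and 12.2%. The cluster led by Itm2a and Tox went the other way, at 4.01% and 1.35%, and that led by Gzmc and Xcl1 held 0.568% and 0.529%. Being unnamed, the cluster led by Itm2a and Tox was not counted as thymocyte-like. Values outside the thymocyte-like clusters therefore include it.

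**Figure D1:**
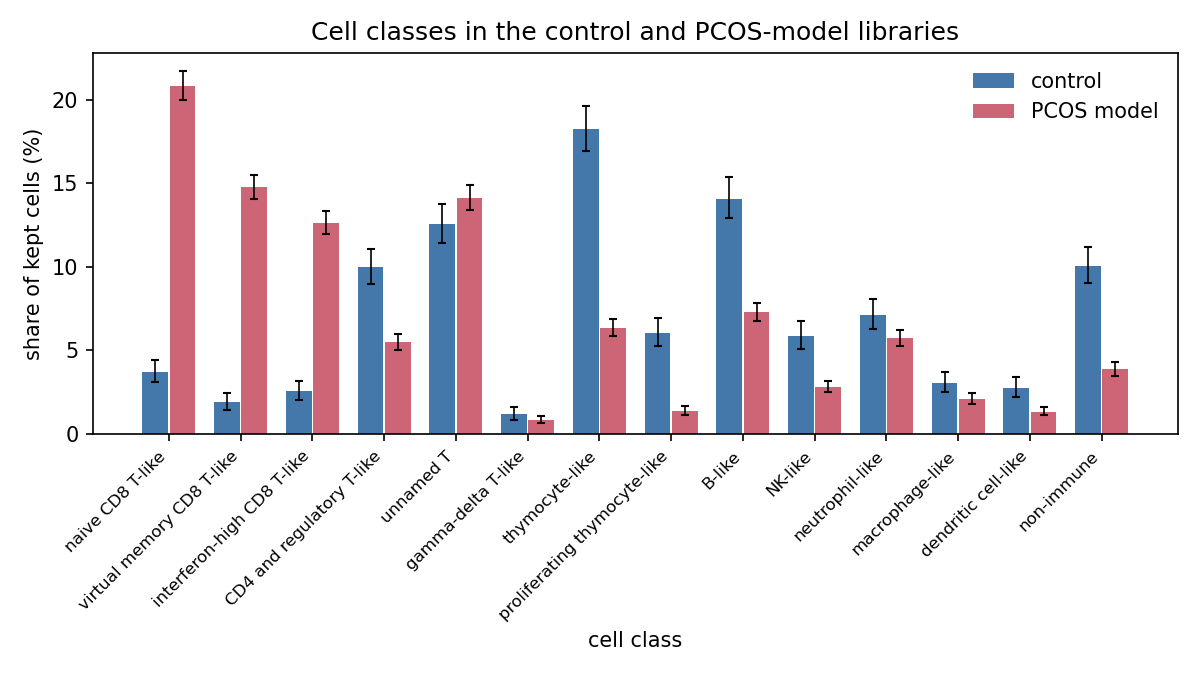
Share of kept cells (%) in each cell class for the control (blue) and PCOS-model (red) libraries, 1 library each, with exact 95% binomial intervals for counting error. Virtual memory CD8 T-like cells were 1.89% and 14.8%, and thymocyte-like cells without the proliferating cluster 18.3% and 6.35%.

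The TCR libraries gave a second view of the same T cells that used no clustering. Among cells with a productive TCR beta chain, those with Cd8a or Cd8b1 and without Cd4 predominated in the PCOS-model library. Cells with both coreceptors, the state of cortical thymocytes, were the largest group in the control library. CD8 T cells made up 29.6% of 948 control cells (26.7 to 32.7) and 80.9% of 2116 PCOS-model cells (79.2 to 82.6), a log2 ratio of 1.45. With Cd8 UMIs above Cd4 UMIs as the gate, which takes in many double-positive cells, the shares were 63.8% and 89.5% (log2 ratio 0.49). Over CD8 and CD4 T cells alone they were 57.7% and 94.2%. CD4 T cells made up 21.7% and 5.01%, double-positive cells 37.03% and 10.02%, and cells with neither 11.6% and 4.06%. Of the double-positive cells, 84.6% and 71.7% lay in thymocyte-like clusters. Outside those clusters CD8 T cells were 38.1% and 87.1% of cells with a beta chain. Thymocyte-like clusters also supplied 20.6% of the control CD8 T cells and 2.45% of the PCOS-model ones. Free RNA was measured beside this in cells that should lack the coreceptor: a Cd8a or Cd8b1 UMI without Cd4 was found in 2.65% of control and 14.96% of PCOS-model neutrophil-like cells (median depths 2728 and 2666 UMIs), and in 4.48% and 13.5% of B-like cells (3724 and 2928 UMIs).

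The next question was whether virtual memory cells made up more of the CD8 T cells. Among all gated CD8 T cells they did: the virtual memory-like subcluster held 22 of 281 control cells (7.83%, 4.97 to 11.6) and 335 of 1712 PCOS-model cells (19.6%, 17.7 to 21.5), a log2 ratio of 1.32. The other 9 subclusters stayed unnamed, and several were led by genes of other cell types. Subclusters led by Gria3 and Itgae held 22.1% and 26.9%, by AY036118 14.9% and 19.4%, by Ifit3 and Ifit1 6.76% and 13.9%, and by haemoglobin genes 2.49% and 9.58%. Those led by Hist1h2ap and Pclaf held 15.7% and 3.27%, by the stroma genes Dcn and Sparc 16.01% and 2.28%, and by Il17a and Il22 8.19% and 1.99%. The subcluster led by Dcn and Sparc also had 7 of 8 thymocyte markers raised, Rag1 and Dntt among them. Those led by the macrophage genes Lyz2 and C1qb held 2.49% and 1.87%, and by the B cell genes Cd79a and Ebf1 3.56% and 1.29%. The denominators differed in make-up, with thymocyte-like clusters at 20.6% and 2.45% of gated cells and CD8 T-like clusters at 30.2% and 65.3%. Among gated cells within the CD8 T-like clusters, virtual memory-like cells were 20 of 85 (23.5%, 15.004 to 33.97) and 314 of 1118 (28.1%, 25.5 to 30.8), a log2 ratio of 0.26 with a counting interval from -0.40 to 0.99. Over those clusters without the TCR gate, the virtual memory cluster held 23.2% and 30.6%, a log2 ratio of 0.40 (0.03 to 0.80). Ly6c2, one of the genes that name this subset, was itself higher across cell classes in the PCOS-model library. With the virtual memory genes kept out of the clustering, the shares among all gated CD8 T cells were 7.12% and 18.5% (log2 ratio 1.37). That value keeps the difference in make-up of the denominators.

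Expression was then compared within gated CD8 T cells. Over all gated cells, the lists of interferon response and naive T cell genes were higher in the PCOS-model library and the proliferation list was lower. Of these, only the interferon response list stayed apart in that direction within the CD8 T-like clusters. The median gene had a log2 ratio of -0.15, so ratios are to be read against that value. The 12 genes with the highest ratios were Ly6c2, Ms4a4c, Cxcl10, Dipk1a, Ifit3, Il6ra, Ifit1, Pglyrp1, Sidt1, Dapl1, Ddx60 and Ust. Ly6c2 (ENSMUSG00000022584), a surface protein of memory-like CD8 T cells and monocytes, was at 469 CPM in the control and 1174 CPM in the PCOS-model library (log2 ratio 1.32, 1.23 to 1.42). Ifit3 (ENSMUSG00000074896) and Ifit1, which restrict viral RNA, had log2 ratios of 1.20 and 1.09. Dapl1, a gene of naive CD8 T cells, was at 142 and 292 CPM. The 12 lowest were Il22, Arg1, Dntt, Ly6d, Endou, Rag1, Arpp21, Hist1h2ap, Ccl21a, Il17a, Slpi and Ccnb1ip1. Rag1 (ENSMUSG00000061311) and Dntt, which rearrange TCR genes in thymocytes, were at 145 and 16.3 CPM and at 213 and 20.2 CPM. Il17a was at 113 and 17.02 CPM, and Il22 had 208 UMIs in the control and 2 in the PCOS-model library (log2 ratio -8.57, -11.95 to -7.02). Within the CD8 T-like clusters some of these genes had too few control UMIs to give a direction, with 0 and 6 UMIs of Il17a, 1 and 16 of Arpp21, 3 and 42 of Ccnb1ip1 and 4 and 58 of Slpi. Ust was at -0.10 there (-0.54 to 0.40), and Cxcl10 at -0.38 (-0.85 to 0.17) in CD8 T cells of T cell clusters.

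Virtual memory genes were mixed. Eomes (ENSMUSG00000032446), a transcription factor of this subset, had a log2 ratio of 0.73 (0.32 to 1.19) in all gated CD8 T cells, and Il2rb (ENSMUSG00000068227), which carries the interleukin-15 signal that maintains it, was at 190.1 and 270.3 CPM. Cxcr3 had a log2 ratio of 0.60 (0.24 to 1.00). Tbx21 was at 18.4 and 29.4, Bcl2 at 185 and 253 and Nkg7 at 446 and 593. Cd44 was level at 69.2 and 64.6 CPM. Ccl5 (1341 and 543 CPM), Klrk1 (18.8 and 6.09 CPM) and Xcl1 (75.3 and 60.3 CPM) were lower in the PCOS-model library. Itga4 (ENSMUSG00000027009), an integrin subunit that is low on virtual memory cells and high on antigen-driven memory cells, was at 153 and 122 CPM. Within the CD8 T-like clusters Ly6c2 (834 and 1400), Cxcr3 (26.02 and 53.03) and Tbx21 (14.6 and 29.8) stayed higher in CPM and Itga4 (159 and 117) stayed lower. Eomes (55.3 and 49.0 CPM), Il2rb (272 and 294 CPM), Cd44 (40.7 and 46.0 CPM) and Bcl2 (296 and 284 CPM) had log2 ratios whose counting intervals spanned 0. Ccl5 stayed lower (429 and 326 CPM), while Xcl1 turned to 14.6 and 26.2 CPM (log2 ratio 0.77, -0.12 to 1.99). In cells thinned to 2000 UMIs, a Ly6c2 UMI was found in 33.97% and 67.5% of gated CD8 T cells (40.6% and 75.5% unthinned), against 3.62% and 13.5% of B-like cells. An Eomes UMI was found in 2.29% and 7.79% (10.7% and 16.3% unthinned), against 0 and 0.962% of B-like cells. Among thinned cells within the CD8 T-like clusters, a Cxcr3 UMI was found in 4 of 84 (4.76%, 1.31 to 11.7) and 96 of 1111 (8.64%, 7.05 to 10.4). A Tbx21 UMI was found in 1 (1.19%, 0.03 to 6.46) and 57 (5.13%, 3.91 to 6.60). These intervals overlapped, as did those of Itga4 (28.6%, 19.2 to 39.5, and 19.6%, 17.3 to 22.1). Those of Ly6c2 did not (53.6%, 42.4 to 64.5, and 73.2%, 70.5 to 75.8). Thinning left out 19 and 55 CD8 T cells and 59 and 126 B-like cells, whose full median depths were 6286 and 5099 UMIs for CD8 T and 3724 and 2928 for B-like cells.

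**Figure D2:**
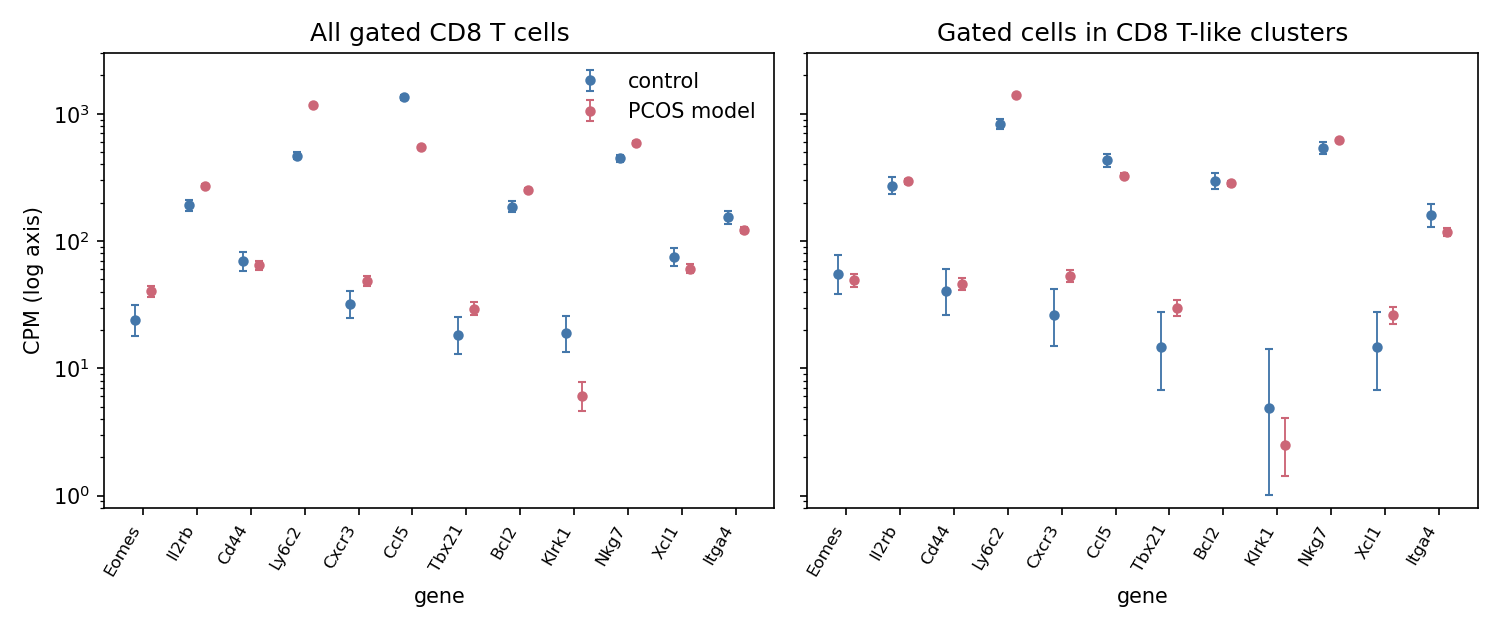
CPM (log axis) of the virtual memory genes and Itga4 in all gated CD8 T cells (left) and in those within CD8 T-like clusters (right), for the control (blue) and PCOS-model (red) libraries, 1 library each, with exact 95% Poisson intervals for counting error. Ly6c2 was higher in the PCOS-model library in both panels, while Eomes was higher in the left panel and not in the right.

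Within the CD8 T-like clusters, the 12 highest genes were Ly6a, Nfatc2, Mphosph8, Cxcr3, Stat4, Ms4a4c, Ifi214, Dipk1a, Psmd1, Ep300, H2-DMa and Trafd1. Ly6a, an interferon-induced surface protein, was at 107 and 242 CPM, and Stat4, which carries interleukin-12 signals, at 97.6 and 189 CPM. The 12 lowest were Ikzf2, Cks2, Rgs2, Bsdc1, Zfand2a, Avl9, Dcaf13, Unc45a, Slc25a40, Per1, Utp14a and Rundc3b. Ikzf2, a transcription factor of regulatory and innate-like T cells, was at 53.7 and 21.7 CPM. This set was added after the data were seen and has 85 control cells.

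Gene lists described the same contrast. The interferon response list had a median log2 ratio of 0.63 in gated CD8 T cells with all 14 members higher, at percentile 100 of 10000 matched random lists. It was 0.27 within the CD8 T-like clusters (12 of 14 higher, percentile 99.99). By cluster, without the TCR gate, it was 0.02 in the virtual memory cluster (7 of 14 higher, percentile 68.7) and 0.15 in the naive cluster (11 of 14 higher, percentile 96.6), with counting ranges that spanned 0. The virtual memory list was at 0.45 (percentile 99.98) and 0.17 (percentile 99.4). This list was not higher in CD8 T cells alone. It was at 1.52 in thymocyte-like cells, 1.11 in CD4 and regulatory T-like cells and 0.83 in gated CD4 T cells, but at -0.02 in NK-like cells. It was at 1.06 in the naive cluster and 0.33 in the virtual memory cluster. Both clusters are without the TCR gate, and so with the difference in Cd8 detection given above. Cd8a and Cd8b1 were also higher in CD4 and regulatory T-like cells of the PCOS-model library. A Cd8a or Cd8b1 UMI was read in 3.54% and 16.1% of neutrophil-like cells. RNA of CD8 T cells may thus enter the values of other classes, and they are not read as changes in those cell types. The cytotoxicity list was at 0.37 (percentile 99.98) and 0.32 (percentile 99.5), with Gzmm higher and Gzmk and Gzma lower among all gated cells. The effector memory list was lower in both, at -1.20 (0 of 10 higher) and -0.48 (0 of 6 higher), with S100a4 and Anxa2 lowest among all gated cells. The naive T list was at 0.38 (percentile 99.9) in all gated cells but at -0.10 (percentile 6.78) within the clusters. Some lists differed widely between these sets, over different numbers of counted members: proliferation was at -2.03 (12 members) and -0.08 (6), inhibitory receptors at -0.90 (9) and 0.10 (3), and cytokines and chemokines at -0.32 (7) and 0.31 (6). The counting ranges of these 3 within the clusters spanned 0. The JAK-STAT list was at 0.10 in both (percentiles 97.7 and 97.8). Steroid receptors and response genes were at -0.50 and -0.26, tissue residency at -0.16 and 0.10, early activation at -0.01 in all gated cells and dissociation stress at 0.16 and 0.07.

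**Figure D3:**
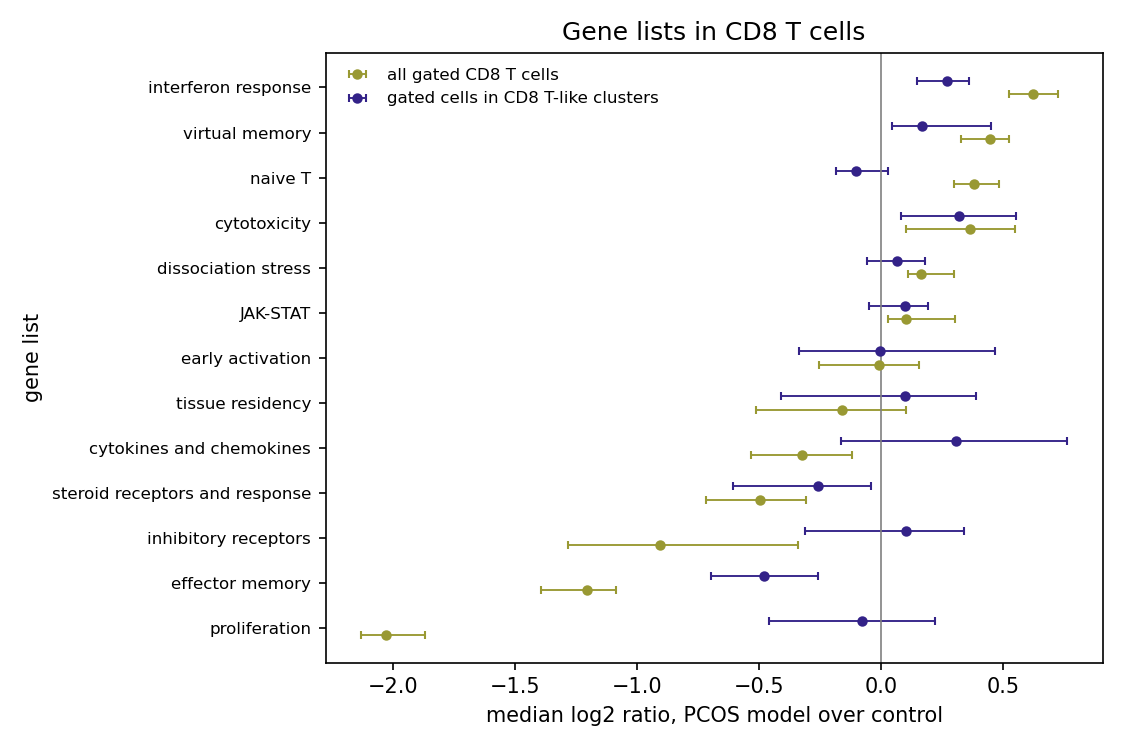
Median log2 ratio (PCOS model over control) of each gene list in all gated CD8 T cells (olive) and in those within CD8 T-like clusters (indigo), from 1 library per group, with 95% ranges for counting error. The proliferation list was at -2.03 and -0.08, and the interferon response list at 0.63 and 0.27.

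Interferon response genes were also higher in several other classes. The list was higher in the PCOS-model library in thymocyte-like (median log2 ratio 1.53), NK-like (0.62), stroma-like (0.62) and B-like cells (0.45), and lower in gated CD4 T cells (-0.35) and CD4 and regulatory T-like cells (-0.26). In neutrophil-like cells it was at -0.12 (percentile 25.2) with a counting range that spanned 0. RNA of CD8 T cells read in other classes was not told apart from a change within them. In gated CD4 T cells (206 and 106 cells) the highest genes were Clec4e, Ccrl2, Ier3, Hdc, Nlrp3 and Ovgp1, and the lowest Ccl7, Ccl12, Ccl2, Ccl4, Apoe and Tgfbi. Many of these are known from neutrophils and macrophages rather than T cells. Ccl7 had 145 UMIs in the control and 0 in the PCOS-model library, at least 24.7-fold lower against a floor of 3 counts over the group. Ly6c2 was at 29.4 and 311 CPM in thymocyte-like cells, which also had higher Il7r, Plac8, Ctsw, Dapl1 and Igfbp4 and lower Hist1h2ap, Ccl5, Dynlt1b, Tgfbr1, Gzma and Fnta. B-like cells had higher Ctsw, Ly6c2, Arl4c, Nkg7, Ms4a4b and Sidt1, several of them known from T and NK cells, and lower Ccl1 (at least 63.7-fold against the same floor), Hist1h2ap, Ciart, Slpi, Neil1 and AY036118. CD4 and regulatory T-like cells had higher Ly6c2, Xcl1, Adgrg5, Ccr9, Cd8a (105 and 375 CPM) and Plac8, and lower Nav2, Gpr183, Gbp2, Ly6c1, Cd40lg and Tnfrsf4. Among neutrophil-like cells the class II antigen presentation list was at 1.10, macrophage inflammation at -0.22 and lipid handling at -0.01. Class II antigen presentation in B-like cells was at -0.12.

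UMIs of the marker lists for free RNA were read in immune cells of both libraries. These sums were not alike in every class, so they cannot be read as free RNA alone. Granulosa genes gave 160 and 174 CPM in neutrophil-like cells, against 32.9 and 25.5 CPM in B-like cells. Over all immune cells, in CPM, granulosa genes gave 29.6 and 16.4, theca and luteal genes 52.9 and 29.6, ovarian stroma genes 12.96 and 17.3, and pericyte and smooth muscle genes 19.2 and 6.72. Endothelial genes gave 123 and 109, epithelial genes 15.2 and 12.95, oocyte genes 1.64 and 1.02, platelet genes 16.7 and 7.09 and erythroid genes 557 and 588. In gated CD8 T cells erythroid genes gave 207 and 673, ovarian stroma genes 130.8 and 231.8, and granulosa genes 26.4 and 5.67. Within the CD8 T-like clusters ovarian stroma genes gave 6.50 and 15.8.

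The TCR libraries then showed whether T cells came from expanded clones. The share of barcodes in shared clonotypes was lower in the PCOS-model library, and no virtual memory cluster barcode of either library was in one. Clonotypes of 2 or more cells held 206 of 984 control barcodes (20.9%, 18.4 to 23.6) and 162 of 2195 PCOS-model barcodes (7.38%, 6.32 to 8.55), a log2 ratio of -1.50. With clonotypes defined by the TRB V gene and CDR3 alone, the shares were 21.4% and 12.3% (log2 ratio -0.80). Thinned to 984 barcodes, the PCOS-model share was 3.34% (2.03 to 4.88 over 1000 draws). TCR recovery also differed, with median TRB UMIs of 7 and 5. A productive TRB was read in 46.7% of control and 27.2% of PCOS-model CD8 T-like cells, and in 53.2% and 32.4% of CD4 and regulatory T-like cells. A shared clonotype is seen only where at least 2 of its cells yield a TCR. Lower recovery can thus lower the share, and thinning to equal barcode numbers does not correct for it. The largest clonotype had 3 barcodes in each library. The shares were 23.2% and 7.93% in CD8 T cells, and 18.1% and 3.60% in CD4 T cells. The virtual memory CD8 T-like cluster had 0 of 36 and 0 of 394 such barcodes, which allows shares of up to 8.33% and 0.761% at a floor of 3 counts (exact upper bounds 9.74% and 0.932%). By TRB sequence alone, 0 of 35 and 5 of 380 were in pairs. Shared clonotypes lay mostly in the 2 clusters with AY036118 among their top genes (57.1% and 26.9% of their barcodes) and, in the control, in proliferating thymocyte-like cells (40.3% and 3.28%). The smaller of the 2 clusters (8 and 158 cells) was also counted as interferon-high, within the CD8 T-like class. Leaving out these clusters therefore takes out part of that class. NK-like cells had 16 of 43 and 8 of 46 such barcodes. Without the clusters with AY036118 among their top genes and all thymocyte-like clusters, the shares were 8.79% and 1.97% (log2 ratio -2.15, -2.88 to -1.44).

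**Figure D4:**
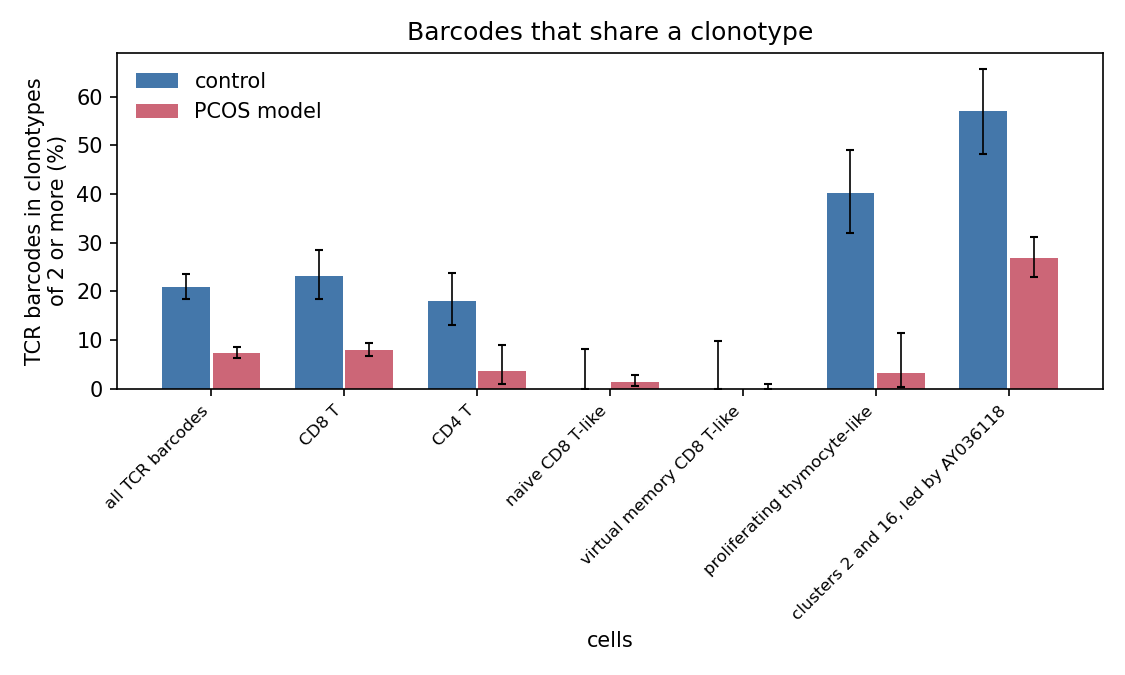
Share of TCR barcodes (%) in clonotypes of 2 or more barcodes by cell group for the control (blue) and PCOS-model (red) libraries, 1 library each, with exact 95% binomial intervals for counting error. Virtual memory CD8 T-like cells had none in either library, and the 2 clusters with AY036118 among their top genes had 57.1% and 26.9%.

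V gene usage differed by a few percentage points. It was counted over all barcodes with the chain, and T cell make-up differed between the libraries. Among kept cells with a beta chain, thymocyte-like clusters held 38.2% and 9.36%, and CD8 T cells 29.6% and 80.9%. Usage was not compared within a cell class, and the genes named are those with the largest differences. TRBV29 was used by 2.52% of control and 6.86% of PCOS-model cells, TRBV16 by 7.23% and 9.17%, TRBV19 by 6.50% and 4.23%, TRBV2 by 3.14% and 0.940%, and TRBV31 by 4.82% and 2.77%. In the alpha chain, TRAV12-2 was used by 0.880% and 5.18%, TRAV12D-3 by 1.76% and 5.47%, TRAV16N by 1.47% and 3.99%, TRAV9-4 by 3.81% and 0.740%, and TRAV14N-3 by 3.81% and 0.888%. A productive alpha chain was read in 341 and 676 barcodes, so that TRAV12-2 rests on 3 and 35 of them.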

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

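The tests in this part were all chosen after the results were seen. One signal lay outside the planned comparisons: 5 TRB sequences (V gene and CDR3 nucleotides) occurred in both libraries, of 870 in the control and 2033 in the PCOS-model library. This is above the floor of 3 counts, and its source was not tested.

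Thymocyte-like cells in ovary-labelled libraries were the first pattern weighed (24.3% and 7.75%). Carry-over of barcodes between libraries is argued against by 0 of 688 thymocyte-like PCOS-model barcodes being control barcodes. Dilution by CD8 T cells does not account for the whole difference, since the share outside CD8 T-like clusters was 26.5% and 14.97% (log2 ratio -0.82). A productive TRB was read in 39.4% and 24.3% of thymocyte-like cells, against 2.91% and 3.72% of B-like, 1.77% and 3.15% of neutrophil-like, 2.86% and 4.05% of stroma-like, and 2.27% and 2.04% of NK-like cells at resolution 2.0, where TRB-bearing cells of the NK-like cluster (22.6% and 18.4%) fall apart from it. Free RNA of thymocytes in B-like, neutrophil-like and stroma-like cells is argued against by a lowest fold of 5.99 (2.42 from the interval bounds). For NK-like cells the comparison cannot decide, since their low share follows from setting the TRB-bearing cells apart. Free RNA of thymocytes in macrophage-like or mature T cells also stays open. The lowest fold over macrophage-like and CD8 T-like cells was 0.844. Mature T cells carry a TRB of their own, so the TRB share cannot decide the question for them. Cells of a thymus collected or processed beside the ovaries, or immature T cells in the ovary, may also be the source, and for the log2 ratio of -1.65 these cannot be told apart because no thymus library was analysed here.

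The larger CD8 T-like share was the second. A gate or recovery that favoured all T cells is argued against by the log2 ratio of CD8 T-like over CD4 and regulatory T-like cells, 3.42 (3.15 to 3.70). CD4 T cells that lost Cd4 transcripts, or lower depth, stay open. A Cd8a or Cd8b1 UMI was read in 95.5% of PCOS-model cells of the CD8 T-like clusters (94.9 to 96.1), against 71.0% in the control. In neutrophil-like cells, which should lack it, at least 1 such UMI was read in 3.54% and 16.1%. Cd8a and Cd8b1 were also higher in CD4 and regulatory T-like cells of the PCOS-model library. A CD4 T cell there may thus carry a Cd8 UMI, so the 95.5% cannot decide the question. Letrozole, or a gate, yield or batch that favoured CD8 T cells, may underlie the log2 ratio of 2.56, and these cannot be told apart with 1 suspension per group.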

How the results depend on the processing

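Alternatives chosen after the data were seen were rate-based doublet removal, the gates by CD8 T-like or thymocyte-like clusters, CD8 over CD8 and CD4, clustering without the virtual memory list, and TRB clonotypes without the clusters with AY036118 among their top genes and the thymocyte-like clusters. Values are log2 ratios. Of 1125 values under alternatives, 1075 kept their sign, 918 lay inside the original counting interval, and 28 counted as reversed. The others that changed sign had an original interval that spanned 0. Of 68 values each for the named CD8 T cell genes, 13 stayed inside the interval in CD8 T cells of T cell clusters, 12 within CD8 T-like clusters and 37 in thinned cells. No paired analysis was possible because each group has 1 library and no result comes from a test, and leaving out a library was not possible either. Depth, gate and batch are confounded with group.

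The CD8 T-like share was 1.70 at resolution 0.5, where no cluster was named CD4 and regulatory T-like, and its range was 1.70 to 2.63. The thymocyte-like share was -1.81 with rate-based doublet removal. B-like (-1.11 to -0.95) and neutrophil-like shares (-0.41 to -0.24) stayed within their intervals. The CD8 share of T cells was 0.49 with Cd8 above Cd4 UMIs, 1.15 in thinned cells, 1.19 without thymocyte-like clusters and 0.71 over CD8 and CD4. The virtual memory share was 0.26 in the TRB gate within CD8 T-like clusters and 0.40 without the TRB gate. Over all gated CD8 T cells it was 1.37 when clustered without the virtual memory list. Clonal expansion was -0.80 for TRB clonotypes. It was -1.56 for TRB clonotypes without the clusters with AY036118 among their top genes and the thymocyte-like clusters. For 3 or more cells it was -1.16, from 6 barcodes in each library, with an interval that spanned 0 (-3.06 to 0.75). The cause was not tested, except that fewer thymocytes enter the cluster gates by construction.

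Under median-of-ratios scaling the naive T list was 0.53, virtual memory 0.59, effector memory -1.05 and interferon response 0.77. Within CD8 T-like clusters they were -0.10 (reversed), 0.17, -0.48 and 0.27, and cytokines and chemokines (0.31) and inhibitory receptors (0.10, 3 members against 9) reversed, all 3 with counting ranges that spanned 0. Genes that reversed there were Ust (-0.10), Arpp21 (0.0775), Il17a (0.32), Slpi (0.32), Ccnb1ip1 (0.22), Il7r (-0.10), Rgs1 (0.10), Gzma (0.0775), Ccl3 (0.28), Pdcd1 (0.0775), Tigit (1.26), Ier3 (0.39), Hspa1b (-0.16), Eomes (-0.19), Bcl2 (-0.0612) and Xcl1 (0.77). All 16 had counting intervals that spanned 0, and for Il17a, Pdcd1 and Tigit, with 0 control UMIs, the sign rests on the 0.5 UMI added. In CD8 T cells of T cell clusters, Cxcl10 (-0.38), Il17a (0.79), Slpi (0.65), Ccnb1ip1 (0.24), S100a4 (0.15), Ccl3 (0.67) and Ier3 (1.02) reversed, 6 of 7 with intervals that spanned 0. As a mean over cells, Ccl3 (0.0327) and Cd8a (-0.15) reversed. The 10 V gene differences and 48 values in other classes stayed within their intervals.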

Other observations

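The tests in this part were chosen after the results were seen. Barcodes with the same TRB sequence came almost wholly in pairs: 101 pairs in the control and 133 in the PCOS-model library, with 92 and 114 of them inside 1 cluster. In the virtual memory CD8 T-like cluster 0 of 35 and 5 of 380 (1.32%) barcodes were in pairs. In the 2 clusters with AY036118 among their top genes, 58.6% and 44.3% were. These shares cannot decide whether pairs come from division of virtual memory CD8 T cells, since such cells may lie outside their named cluster. At resolution 2.0, a cluster with AY036118 among its top 10 genes also had Gzmm and Ctla2a there, both top 10 genes of the virtual memory cluster. One thymocyte-like cluster of low depth had 60.4% and 65.4% in pairs. The same cell read under 2 barcodes is a candidate explanation that stays open. Rare transcripts shared by partners were set against random pairs of the same cluster. In the clusters with AY036118 among their top genes, 27.8% of control and 12.6% of PCOS-model pairs lay in the top 2.5% of random pairs. Their lower bounds, 14.2% and 6.70%, were both above that 2.5%. The test asked for a lower bound over 10% in both libraries, which the PCOS-model library did not reach. In that thymocyte-like cluster the share was 33.3% in each library, from 12 and 6 pairs with lower bounds of 9.92% and 4.33%. Among proliferating thymocyte-like cells of the control it was 14.8% of 27 pairs, with a lower bound of 4.19%. Cells of 1 clone may share transcripts too. In proliferating thymocyte-like cells, median AY036118 was 14845 CPM in paired and 368 CPM in unpaired control barcodes, and 7893 (6 barcodes) and 246 CPM in the PCOS-model library. In the 2 clusters with AY036118 among their top genes, paired and unpaired medians were closer, at 17135 and 14161 CPM in the control and 13661 and 10139 CPM in the PCOS-model library. If pairs are single cells, the clonotype shares above overstate expansion in both libraries.

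The expression libraries had 10 barcodes in common. The invariant NKT chain TRAV11 with TRAJ18 was read in 2 of 341 control and 1 of 676 PCOS-model barcodes.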
